A study of Mus musculus with 2 samples.

How the data were processed

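The samples were 2 DNase-seq libraries of thymus from male B6CASTF1/J mice aged 14 days, labelled as separate biological replicates of 1 group. Coordinates were in mm10 per the labels, and chromosome lengths of the reference sequence used here (GRCm38.p6) matched that build. The aligner, the peak caller and the footprint caller are not given in the sources used here. The animals are hybrids of 2 strains and the reference is that of C57BL/6J, so reads of the CAST/EiJ copy with mismatches could have been lost in mapping, and accessibility at such sites could be understated.

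Per the sample records deposited with the data, each library has 2 narrow peak lists, 1 list of footprints and 1 list of intervals with the false discovery rate (FDR) of their cleavage rate, all derived by the authors from the library's own alignments and not from pooled libraries. The deposited signal of a peak is the authors' value, scaled within each library by a constant that the sources used here do not state. All values below 1000 steps were whole multiples of 1 smallest step per library (tolerance 0.05 steps). The signal was used to describe, rank and filter peaks within a library, and to compare libraries as ratios at shared peaks. In departure from this, 1 alternative kept peaks with a signal of at least 1 in both libraries, and clusters of weak peaks were counted with a limit scaled by that ratio. Named genes and peaks were also ranked by, and given as, the mean ± SD of the unscaled signals of both libraries. Such an SD includes the general difference between the libraries (median ratio 0.80 at shared peaks) and is not variation of the gene alone. The deposited p-value column of the footprint lists holds 0.01 throughout, and the deposited FDR values, a kind of q-value, are listed only for intervals below 0.05. These intervals covered 36.6 Mb in replicate 1 and 45.5 Mb in replicate 2.

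Of the 2 peak lists of a library the one with fewer peaks served as the main list. Every one of its peaks contained an interval with an FDR of at most 0.001, and every peak of the longer list (108620 and 134552 peaks) one of at most 0.0498 or 0.0499. The column for the summit holds the constant 75, so peak centres were used in place of summits. Total reads per library were not used here, and the precision of a share of peaks was given as a 95% Wilson interval, which covers counting error only. A peak list holds only what passed the caller, so the absence of a peak sets no upper limit.

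Computations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. Genes, exons and start sites came from GENCODE vM21 basic. A peak counted as shared when it overlapped a peak of the other replicate by at least 1 bp. Its location was that of its centre, with promoters defined as within 1 kb of any annotated TSS, then exons, introns and intergenic sequence. Gene lists (21, with markers of T cells, of the other cells of the organ and of unrelated tissues) and consensus motifs (29) were fixed before the data were examined, as were the tests and most alternatives. The background for gene lists was the 21911 protein-coding genes on chromosomes with a peak. Trac and Trbc1 of the T-lineage list, Ctsv and Tf had no protein-coding entry under these symbols and were not tested.

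Promoter peaks of lists were tested per replicate with a two-sided Fisher's exact test against all other protein-coding genes. Peaks within 50 kb of the 5'-most TSS were compared with 10000 random lists of the same size matched on the decile of gene density. Motif matches on either strand in the 150 bp at the centre of distal peaks were compared with a dinucleotide-shuffled copy of each window by an exact McNemar test. Footprints over motif matches were compared with matches of the reversed consensus, leaving out 1 motif that is its own reverse. All p-values were adjusted by Benjamini-Hochberg within a replicate, and a list or motif was called only where both replicates passed 0.05 in the same direction. These p-values compare genes, windows or matches within a library, which are not independent replicates of the animals.

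The tests were tried on simulated data. In 420 simulated lists with an odds ratio of 4, 52.6% were called, with an odds ratio of 0.25, 71.7%, and with no effect 0, over 21911 genes. Of 105 lists with 2-fold more peaks around their genes, 52.4% were called. In that trial counts were shuffled over genes and the random lists were not matched on gene density. It therefore did not try the matched test reported here. All 29 motifs planted in 2% of 20000 windows were called and none of 29 without planting. For footprints over motifs, footprints added over a random part of the RUNX matches were called (1 of 28 motifs) and footprints placed at random gave 0, while footprints added over CTCF matches were not called. The reversed CTCF consensus had 7 matches, and the cause was not tested.

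The genes named were chosen by a rule fixed together with the tests. It took the 8 T-lineage genes with the most peaks within 50 kb and any member of that list with a promoter peak in neither replicate. From each other list it took the 2 genes with the highest mean promoter signal among those with a promoter peak in both replicates and the first 2 by alphabet among those with one in neither. It also took the 10 strongest shared peaks, the 10 genes with the most peaks and 7 fixed loci (Cd4, Cd8a, Rag1, Bcl11b, Ptcra, Cd3e and Trac). Not every gene that the rule takes is named. Alternatives were the longer lists, an equal number of the strongest peaks, other windows, overlaps, backgrounds and matchings, and each replicate alone. Random lists matched on promoter CpG content, peaks with a signal of at least 1, and the comparison of one replicate's main list with the other's longer list were added after the data were seen. Genes named around clusters of weak peaks, gene families, receptor loci and sex chromosome genes were also chosen after their values were seen. The series has no second group, so no test between groups was made.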

Results

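DNase-seq was carried out on whole thymus from male B6CASTF1/J mice at 14 days of age. These mice are first-generation hybrids of C57BL/6J and CAST/EiJ. In this assay DNase I cuts chromatin where it is accessible, and clusters of cuts mark promoters, enhancers and other regulatory elements. The thymus is the organ in which T cells develop, and its cells are mostly thymocytes among epithelial cells, macrophages, dendritic cells, fibroblasts and endothelium. The series holds 1 group with 2 biological replicates, so there is no treated or control group, and the design allows a description of the accessible chromatin, a comparison between the replicates and a comparison of gene groups within each library. The label of replicate 1 names 3 males, and no number of males was taken from that of replicate 2. Whether replicate 1 is a pool of animals is not given in the sources used here, so the replicates need not stand for the same number of animals.

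The stricter deposited peak list held 75866 peaks in replicate 1 and 90671 in replicate 2. They covered 14.2 and 17.8 Mb, or 0.522% and 0.652% of the mm10 genome, with a median width of 180 bp in both. Total read counts were not used here. Each peak carries the authors' signal value, and all signal values below 1000 steps were whole multiples of a smallest step of 0.00731 in replicate 1 and 0.00381 in replicate 2, within a tolerance of 0.05 steps. If the signal is a density scaled to the number of cleavages, which the sources used here do not state, replicate 2 would be 1.92 times as deep as replicate 1. The median signal was 1.78 in replicate 1 and 1.17 in replicate 2.

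The first question was how far the accessible sites of both replicates overlapped. Of the replicate 1 peaks, 70208 (92.5%, 95% Wilson interval 92.4 to 92.7) overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks 70139 (77.4%, interval 77.1 to 77.6) overlapped one of replicate 1. Covered bases alone would give 1.36% and 1.13%. Peaks found in only one replicate were weaker, with a median signal of 0.592 in replicate 1 and 0.484 in replicate 2 against 1.97 and 1.64 for shared peaks. Over the 70208 shared peaks the log2 signals of the replicates correlated with a Pearson r of 0.984 and a Spearman rho of 0.979. This correlation is across peaks, which are not independent replicates. The signal of replicate 2 was lower at shared peaks, with a median ratio to replicate 1 of 0.80 and a log2 ratio of −0.32 (quartiles −0.51 and −0.12).

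The 10 shared peaks with the highest mean signal lay at promoters, with 1 exception. That exception was also the highest, at X:169998261-169998420 (mm10) in an intron of Mid1, a gene that crosses the boundary of the pseudoautosomal region, with a signal of 120.4 ± 7.48 (SD, n = 2). It was the only peak of the 10 with a higher signal in replicate 2 (125.7) than in replicate 1 (115.2). The second was at 17:6430021-6430180, 11 bp from the transcription start site (TSS) of Dynlt1b, a dynein light chain gene with near-identical copies, with 112.4 ± 37.5. The other 8 lay within 200 bp of the start sites of Mplkip, Dnpep, Hjurp, Myo10, Fzr1, Esrra, Ing2 and Eif5a. Their mean signals ran from 73.4 ± 22.6 at Mplkip to 56.5 ± 16.1 at Eif5a, the translation factor gene (SD, n = 2 for each). Signals were not scaled between the libraries, so the SDs of signals here and below include the general difference between replicates.

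Promoters were the most enriched class of regions. Within 1 kb of an annotated start site lay 33.5% ± 1.69 of the peaks (SD, n = 2), against 4.25% of the genome, 7.89-fold more. Introns held 35.6% ± 1.03, intergenic sequence 25.99% ± 0.432 and exons 4.84% ± 0.235, against 39.2%, 53.7% and 2.82% of the genome. Promoter peaks were also stronger, with a median signal of 3.47 in replicate 1 and 2.31 in replicate 2 against 1.41 and 0.942 in introns. A promoter peak was present at 13077 of 21911 protein-coding genes in replicate 1 (59.7%) and at 13437 in replicate 2 (61.3%). Both replicates had one at 12964 genes, and neither had one at 8361.

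Genes of the T-cell lineage stood out at their promoters. All 48 tested members of the T-lineage list, which holds surface receptors, recombination genes and transcription factors of thymocytes, had a promoter peak in both replicates (Fisher's exact test, two-sided, Benjamini-Hochberg over 21 lists, adjusted p = 6.83e-10 in replicate 1 and 1.95e-09 in replicate 2). Of the 30 genes of T-cell receptor signalling, 29 had one in replicate 1 and 30 in replicate 2 (exact adjusted p = 1.33e-05 and 2.1e-06). The highest promoter signals of that list were at Nck1, an adaptor gene, with 34.6 ± 11.1, and at Bcl10, which links the receptor to NF-kB, with 31.9 ± 11.04 (SD, n = 2). All 25 genes of the apoptosis and negative selection list had a promoter peak in both replicates, led by the survival gene Bcl2l1 (45.8 ± 14.7) and by Apaf1 of the apoptosome (42.2 ± 12.2). The same held for all 25 genes of Notch, Wnt and cytokine receptor signalling, led by Ifngr1 (37.8 ± 12.6) and Stat3 (37.3 ± 9.22), for all 35 cell cycle genes, led by Ccne1 (35.6 ± 5.80) and the replication helicase gene Mcm2 (28.6 ± 9.24), and for all 32 housekeeping genes, led by Actb (38.0 ± 11.3) and Ubb (34.5 ± 11.1). The adjusted p of these 4 lists lay between 1.27e-07 and 2.41e-05. Against random lists matched on promoter CpG content, chosen after the shares were seen, the cell cycle list was no longer called (permutation adjusted p = 0.0546 and 0.0813), and the other 5 were.

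In 7 lists of markers of other cell types and tissues, fewer genes had a promoter peak than among other protein-coding genes in both replicates. Of 25 liver genes only Apob, which encodes the protein of low-density lipoprotein, had one, in both replicates, with a signal of 0.912 ± 0.00901, and Afp and Ahsg had none (exact adjusted p = 5.38e-08 and 2.03e-08). Of 20 granulocyte and mast cell genes, 2 had a promoter peak, Il5ra (1.497 ± 0.456) and Cxcr2 (1.399 ± 0.398), while the antimicrobial peptide gene Camp and the transcription factor gene Cebpe had none (exact adjusted p = 1.33e-05 and 9.92e-06). Of 23 erythroid and megakaryocyte genes, 3 had one in replicate 1 and 4 in replicate 2, among them Epor (3.50 ± 1.08), and the heme synthesis gene Alas2 and Epb42 had none (exact adjusted p = 1.33e-05 and 7.8e-05). Muscle genes had 7 of 28, with Actn3 (17.4 ± 4.74) and Actn2 (9.73 ± 2.70) but not the actin genes Acta1 and Actc1 (exact adjusted p = 0.000647 and 0.00026). Testis germ cell genes had 6 of 24 in replicate 1 and 7 in replicate 2, with Zpbp (12.6 ± 2.74) and Dazl (8.97 ± 2.00) but not Acr and Akap4 (exact adjusted p = 0.00128 and 0.00462). Fibroblast and mesenchyme genes had 8 of 23, with Thy1 (9.46 ± 2.04), which is also in the T-lineage list, and Pdgfra (5.50 ± 0.599) but not Acta2 and Col1a2 (exact adjusted p = 0.03 and 0.0263). Adipocyte genes had 5 of 17, with Acsl1 (23.9 ± 5.52) and Slc2a4 (18.8 ± 3.74) but not Adipoq and Adrb3 (exact adjusted p = 0.0232 and 0.0186). Against lists matched on promoter CpG content, only the liver and testis lists were called lower. The testis call was lost with the longer peak lists (41.7% of its genes). The adipocyte call was lost with the longer lists (44.1%) and with promoters of 2.5 kb (55.9%), and the fibroblast and mesenchyme call with the longer lists (60.9%), with promoters of 2.5 kb (52.2%) and with the 5'-most start site alone (34.8%).

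The remaining 8 lists were not called, which does not show that their shares were those of other genes. Among them were several of the other cell types of the organ. Of 30 thymic epithelium genes 18 had a promoter peak in each replicate (exact adjusted p = 1 and 0.897), with the chemokine gene Ccl25 (20.5 ± 5.31) and Ly75 (15.95 ± 4.43) and without Cldn3 and Cxcl12. Macrophage and dendritic cell genes had 12 of 27 in replicate 1 and 11 in replicate 2 (exact adjusted p = 0.166 and 0.064), with Cebpa (4.20 ± 0.744) and without Adgre1 and C1qa. B cell genes had 9 and 11 of 20 (exact adjusted p = 0.296 and 0.716), with the B-lineage factor gene Ebf1 (9.75 ± 2.97) and Cr2 (9.38 ± 2.15) and without the B-cell receptor gene Cd79a. Natural killer and innate lymphoid genes had 8 and 9 of 18 (exact adjusted p = 0.285 and 0.421), with Id2 (18.7 ± 7.45) and Gata3 (9.26 ± 2.51), a factor that thymocytes also need, and without Fcer1g and Klra4. Regulatory and effector T-cell genes had 14 of 23 in each (exact adjusted p = 1 in both), with perforin, Prf1 (5.24 ± 0.987), and Tnfrsf18 (5.16 ± 1.56) and without Gzmb and Havcr2. Early progenitor genes had 13 of 17 (exact adjusted p = 0.285 and 0.295), with Kit (13.1 ± 3.21) and Hlf (9.41 ± 2.06) and without Cd34 and Hoxa9. Endothelial genes had 8 of 21 (exact adjusted p = 0.0717 and 0.0619), with Pecam1 (3.37 ± 0.941) and Eng (2.90 ± 0.522) and without Aplnr and Cdh5. Neuronal genes had 16 of 28 in replicate 1 and 19 in replicate 2 (exact adjusted p = 0.937 and 0.657), with Eno2 (4.36 ± 0.694) and Syn1 (3.26 ± 1.00) and without Chrna4 and Dcx. Against lists matched on promoter CpG content, none of the 8 was called either. In the mean of both replicates, B cell (50% against 32.0%), natural killer (47.2% against 34.2%) and regulatory T-cell genes (60.9% against 39.2%) lay above the matched lists. Early progenitor, macrophage and thymic epithelium genes did too. Endothelial (38.1% against 52.6%) and neuronal genes (62.5% against 66.6%) lay below. The peak lists hold only called peaks, so a gene without one may still have weaker accessibility.

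**Figure D1:**
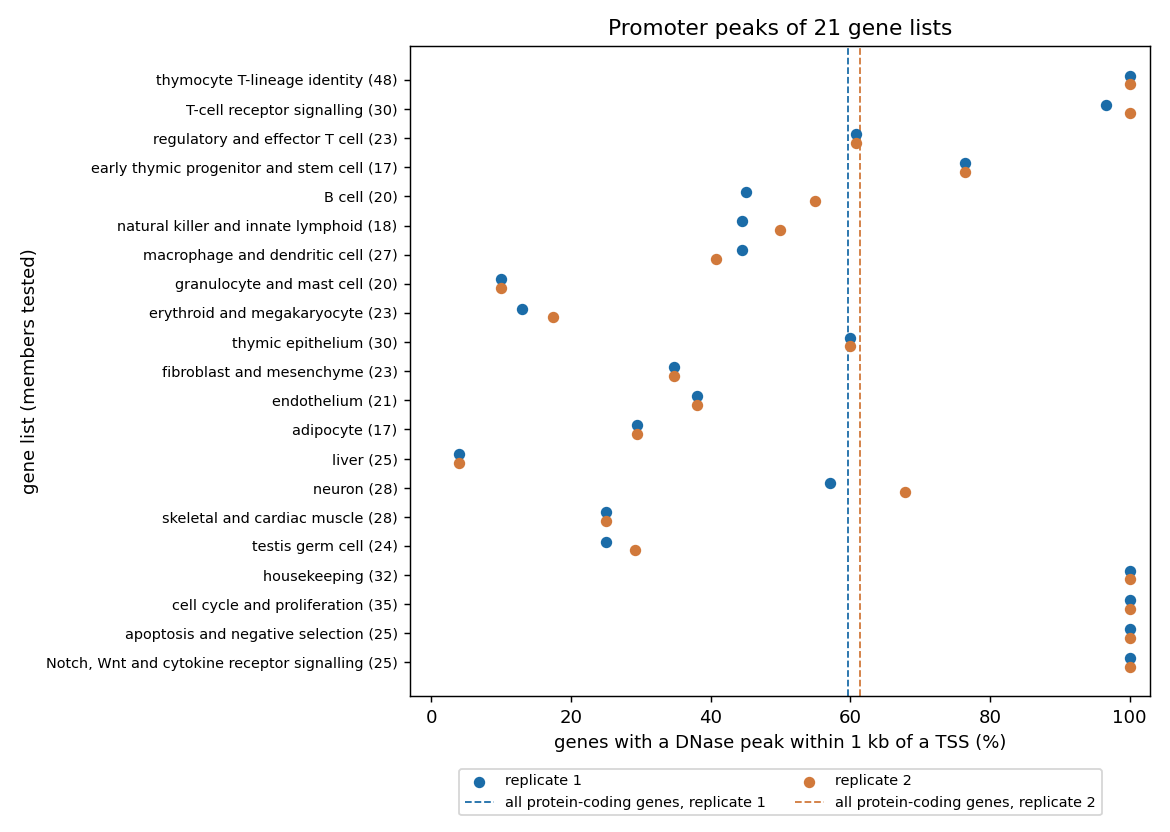
Share of the tested genes of each list with a main-list peak within 1 kb of an annotated TSS, in percent, with 1 point per replicate and dashed lines for all protein-coding genes (59.7% and 61.3%). The T-lineage list reaches 100% in both replicates, and the liver list 4%.

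Around the T-lineage genes, listed peaks were crowded well beyond the promoter. The median member had 17 peaks within 50 kb of its 5'-most start site in replicate 1 and 24 in replicate 2, against medians of 5 and 5.5 in 10000 random lists matched on gene density (central 95% of the random lists, 3 to 7 and 3 to 7.5). The coreceptor genes led the list, with 81 ± 7.07 peaks at Cd8b1 and 79 ± 15.6 at Cd8a, whose windows overlap (SD, n = 2). Tcf7, which encodes the transcription factor TCF1, had 78.5 ± 2.12 peaks, the chromatin organiser gene Satb1 had 41 ± 31.1, the costimulatory receptor gene Cd27 had 39 ± 11.3, the recombinase gene Rag2 had 37 ± 35.4, Cd2 had 35 ± 5.66 and Thy1 had 32 ± 1.41. At Satb1 and Rag2 the replicates differed widely, with 19 and 12 peaks in replicate 1 against 63 and 62 in replicate 2. Some listed peaks overlap each other, as do 6:71372101-71372940 and 6:71372341-71372960 in replicate 2 near Cd8a. The counts are therefore of listed peaks and not of separate sites. With only peaks of signal at least 1, the median T-lineage gene had 16 peaks in replicate 1 and 15 in replicate 2. The random lists then had a median of 3 in each replicate.

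The lists of apoptosis and negative selection (13 and 16 peaks in the median gene), Notch, Wnt and cytokine receptor signalling (11 and 14), T-cell receptor signalling (10 and 12) and housekeeping (11.5 and 13) also lay above their random lists in both replicates. The permutation p, two-sided and adjusted over 21 lists, was 0.00105 for the first 3 and for the T-lineage list, from the smallest p that 10000 lists can give, 0.0002. For housekeeping it was 0.00588 and 0.0176, and the call was lost with windows of 25 kb. No list was called below its random lists in both replicates. The lowest count was that of fibroblast and mesenchyme, with 2 peaks in the median gene (permutation adjusted p = 0.434 and 0.277). This list was called lower when the random lists were matched on gene length. Relative to its random lists, granulocyte and mast cell lay about as low, with 4 and 4.5 peaks against 7 and 8 (permutation adjusted p = 0.332 and 0.277). The lists of B cells, macrophages and thymic epithelium had 7.5 and 10.5, 5 and 6, and 5.5 and 6 peaks in the median gene and were not called.

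**Figure D2:**
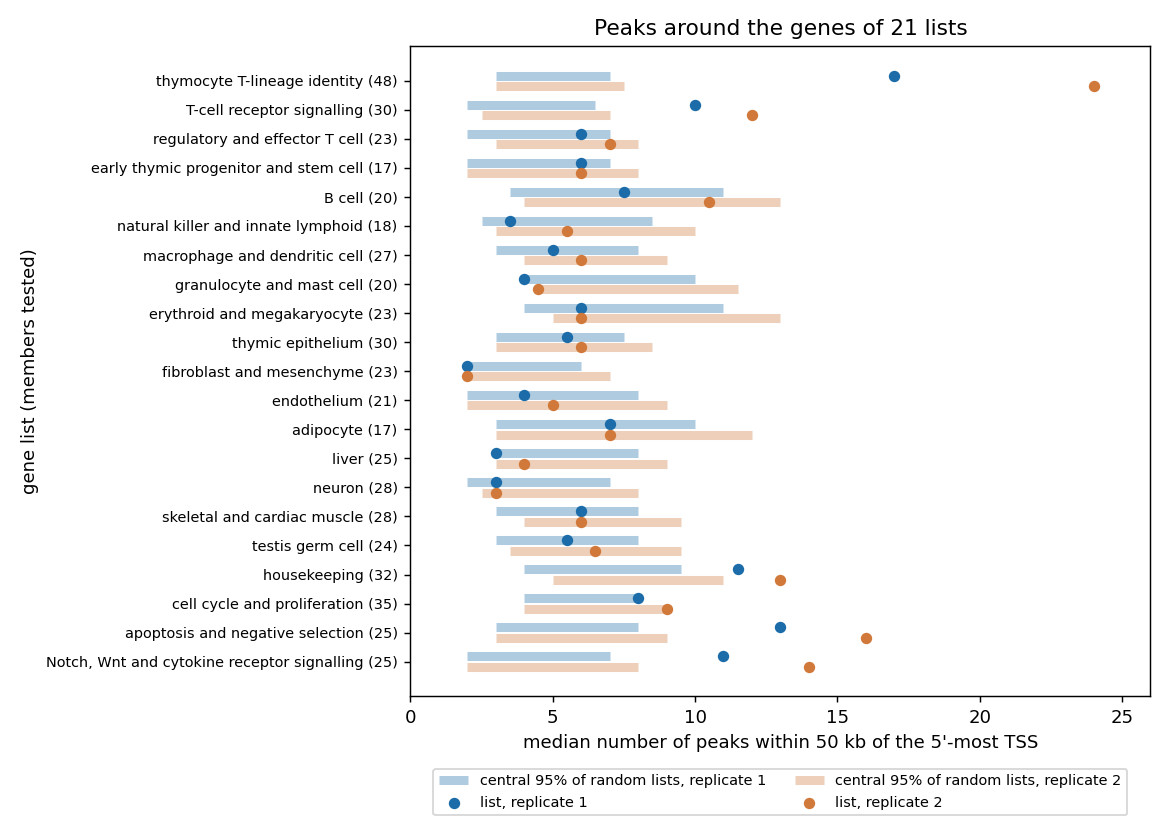
Median number of main-list peaks within 50 kb of the 5'-most TSS of the genes of each list (points, 1 per replicate) with the central 95% of 10000 random lists matched on gene density (bars). The T-lineage list (17 and 24 peaks) lies farthest above its bars, which end at 7 and 7.5.

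Among all protein-coding genes, counting overlapping windows once, Cd8b1 and Tcf7 ranked first and second in the number of peaks within 50 kb. Next came Tap2, a peptide transporter gene of antigen presentation in the major histocompatibility complex, with 59.5 ± 21.9, and Zfp36l2, which encodes an RNA-binding protein, with 53 ± 5.66. Chd3, Cic and Rara, the retinoic acid receptor alpha gene, had 46 each (SD 0, 9.90 and 5.66), Atp5d had 44.5 ± 0.707, the ETS factor gene Fli1 had 44 ± 11.3 and Rbm38 had 43 ± 15.6 (SD, n = 2).

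**Figure D3:**
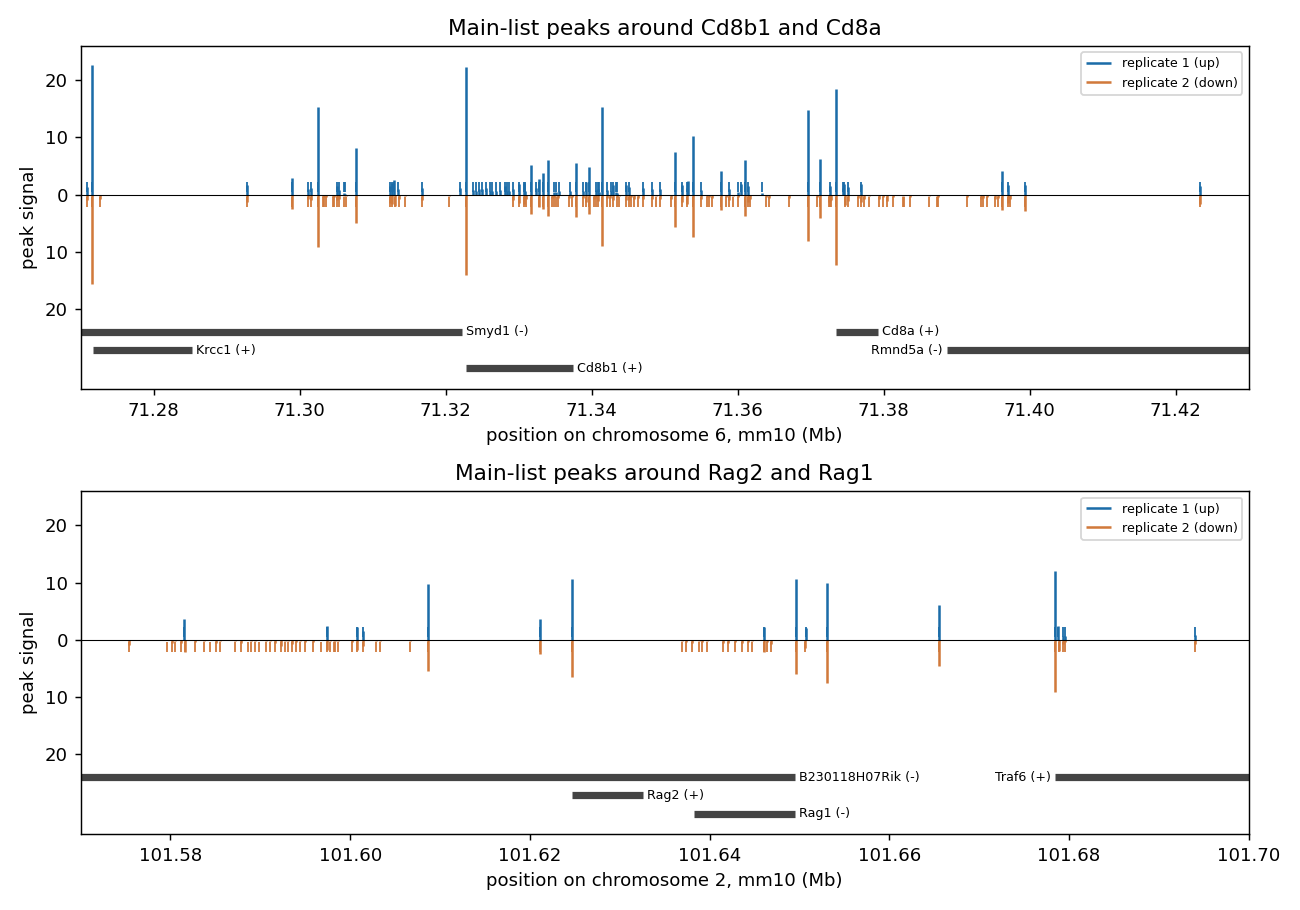
Main-list peaks around Cd8b1 and Cd8a on chromosome 6 and around Rag2 and Rag1 on chromosome 2 (mm10), replicate 1 upward and replicate 2 downward, with line height as the authors' signal, a short tick of fixed height at every peak and bars for protein-coding genes. The tall peaks stand in both replicates, while rows of ticks with low signal appear in replicate 2 on the left of Rag2 and over Rag1, with 62 peaks within 50 kb of the Rag2 start site against 12 in replicate 1. Replicate 1 also has a row of low ticks over Cd8b1, from 6:71323767 to 6:71329240, mostly without counterparts in replicate 2.

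At individual T-cell loci the strongest element was often not the promoter. Cd4, the other coreceptor gene (6:124864692-124888221, minus strand), had its highest peak in intergenic sequence at 6:124903641-124903860, at −15530 bp from the start site in replicate 1, with a signal of 39.3 in replicate 1 and 25.7 in replicate 2, while its promoter peak reached 3.62 and 2.60. The promoter of Cd8a carried the highest peak of its window, at 6:71373381-71373560, with 18.5 and 12.4. At Rag1 the promoter peak had a signal of 10.6 and 6.02, below a peak at −28880 bp that lies at another promoter (11.997 and 9.08). Bcl11b, a factor needed for T-lineage commitment, had a promoter peak of 15.4 and 10.2 placed at −529 bp from the start site, and in replicate 2 an intronic peak 4661 bp downstream was higher (11.4). Ptcra, which encodes the pre-T-cell receptor alpha chain, had a promoter peak of 7.43 and 3.84, and Cd3e had one of 9.17 and 5.67. Their windows held higher peaks at promoters of neighbouring genes, with 31.9 and 18.4 near Ptcra and 33.3 and 25.6 near Cd3e. Trac, the constant gene of the T-cell receptor alpha chain (14:54220521-54224206), had no promoter peak, and its highest peak lay in intergenic sequence past the end of the gene at 14:54227421-54227740, 7060 bp from its start, with 31.0 and 16.7.

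Promoters found in only one replicate did not point to any of the 21 gene lists. No list was called in either direction (Fisher's exact test on the genes with a promoter peak in either replicate, 21 lists per direction). The smallest adjusted p was 0.773 for replicate 1 only and 0.567 for replicate 2 only, and the count at an unadjusted p under 0.05 was 0 and 1. The list nearest to a call was neuron, with 3 of 19 promoters found in replicate 2 only (15.8% against 3.47% of other genes, exact unadjusted p = 0.027). Among the 30 T-cell receptor signalling promoters, 1 was found in replicate 2 only. With the longer peak lists, 1 list was called in each direction, skeletal and cardiac muscle (3 of 11 promoters in replicate 1 only, exact adjusted p = 0.0134) and testis germ cell (5 of 13 in replicate 2 only, adjusted p = 0.00431).

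Motifs were counted in distal peaks, those farther than 1 kb from any start site, and motifs of T-cell transcription factors differed from shuffled sequence in both directions. The CTCF consensus, the site of the insulator protein, matched 9.79% ± 0.864 of the 150 bp windows, 82.3 ± 1.64 times the share in dinucleotide-shuffled copies (SD, n = 2). The ETS consensus, bound by factors such as Ets1 and Fli1, matched 6.97% ± 0.310, 8.01 ± 0.191 times the shuffled share, and the RUNX consensus 8.19% ± 0.302, 2.43 ± 0.0034 times. E-boxes of the E proteins E2A and HEB reached 6.25% ± 0.527 and a ratio of 2.03 ± 0.0773, the TCF1/LEF1 site 2.33% ± 0.0778 and 1.73 ± 0.043, the ROR site 0.468% ± 0.0401 and 3.02 ± 0.468, and the GATA site 1.41% ± 0.0335 and 1.51 ± 0.0148. Of 29 motifs, 20 were more frequent than in shuffled sequence and 7 less frequent in both replicates (exact McNemar test, two-sided, Benjamini-Hochberg over 29 motifs). The 20 were not confined to motifs named after T-cell factors. Among them were PU.1 with a mean ratio of 7.39, MEF2 with 3.67 and IRF with 3.06. MyoD (1.61), OCT (1.59), EBF (1.28) and the erythroid KLF site were also among the 20. A match does not tell which factor binds. The MyoD consensus shares CAGCTG with the E-box, and the PU.1 consensus shares GGAA with that of ETS, so these ratios are not independent. For RUNX the adjusted p was 2.49e-245 and 3.25e-290 over 49520 and 61354 windows, and for GATA 4.08e-12 and 1.74e-14.

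The 7 less frequent motifs were those of NF-kB (ratio 0.887 ± 0.0178), MYB (0.848 ± 0.00192), Ikaros (0.851 ± 0.0241), p53/p63 (0.770 ± 0.0402), SOX (0.773 ± 0.0229), the liver factor HNF4 (0.679 ± 0.0438) and C/EBP (0.489 ± 0.0375). Neither NF-Y (0.982 ± 0.0561) nor HNF1 (1.08 ± 0.516) passed the test. The REST ratio of 189.7 ± 140.5 rests on almost no shuffled matches, and REST sites were in 0.254% ± 0.0268 of the windows. With 100 bp windows NF-kB (0.952), HNF4 (0.672), SOX (0.839) and Ikaros (0.882) were no longer called, although the HNF4 ratio hardly moved. Against flanking genomic windows 1 kb away, 3 of the 7 were above 1, NF-kB at 1.44, MYB at 1.13 and C/EBP at 4.64. In the same comparison the ratios of GATA, IRF and OCT fell below 1, to 0.829, 0.754 and 0.714. MEF2 (1.02) and YY1 (2.16) were not called against flanking windows, while PU.1 was at 5.77. CTCF, ETS, RUNX, TCF1/LEF1, E-box and ROR remained above 1, at 197.1, 5.59, 2.00, 1.69, 3.50 and 2.45. In promoter peaks, NF-Y (5.71), CREB/ATF (22.3) and YY1 (25.4) were above shuffled sequence, and TCF1/LEF1 was not called (1.07).

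**Figure D4:**
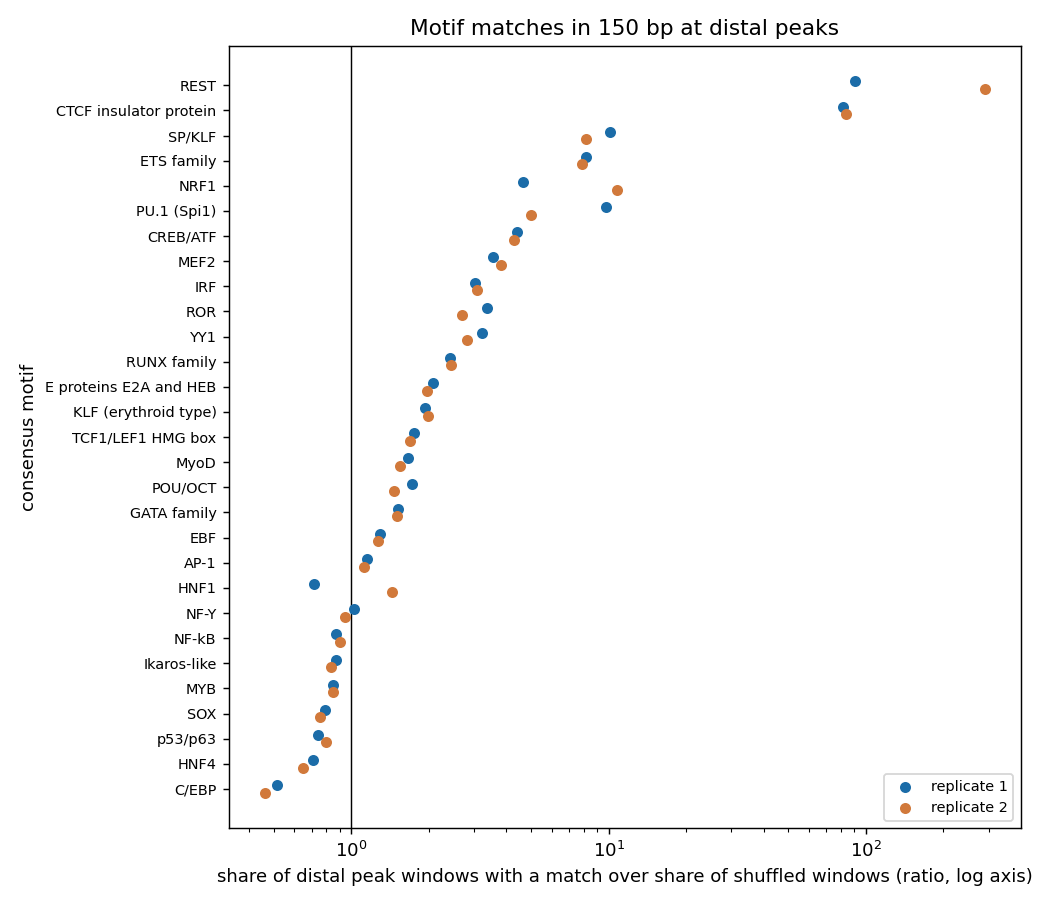
Ratio of the share of 150 bp windows at distal peaks with a match of each of 29 consensus motifs to the share of dinucleotide-shuffled windows, on a log axis with 1 point per replicate. CTCF lies at 81.1 and 83.4, ETS at 8.14 and 7.87, and RUNX at 2.42 and 2.43.

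Footprints, short stretches protected from cutting inside accessible sites, marked nearly every CTCF match but a minority of the matches of most T-cell factors. Of the CTCF matches in main-list peaks, 98.2% ± 1.31 were overlapped by a footprint (SD, n = 2), as were 95.02% ± 0.929 of the matches of REST, a repressor of neuronal genes, 92.3% ± 0.620 for NRF1, 88.5% ± 1.16 for CREB/ATF and 73.03% ± 2.40 for YY1. The share was 50.7% ± 4.80 for TCF1/LEF1, 40.5% ± 1.07 for RUNX, 33.0% ± 0.171 for ETS, 28.9% ± 0.333 for E-boxes, 28.6% ± 1.99 for ROR and 23.2% ± 0.279 for GATA. Set against matches of the reversed consensus, which has the same bases, TCF1/LEF1 (32.5%), RUNX (26.5%), NRF1 (64.5%), CREB/ATF (34.0%) and NF-Y (49.0% ± 1.78 against 30.9%) were footprinted more often. CTCF, HNF4, C/EBP and the erythroid KLF site were as well, so that 9 of 28 motifs were above their reversed consensus and 4 below (Fisher's exact test, two-sided, Benjamini-Hochberg over 28 motifs). In distal peaks alone CTCF, NRF1, C/EBP and the KLF site were no longer called, although 97.2% and 99.2% of the distal CTCF matches were footprinted, with 1 reversed match in each replicate, and the C/EBP share was 50% and 48.6% against 13.3% and 12.5%. The mean NRF1 ratio was 1.29 there, against 1.43 in all main-list peaks. C/EBP and the KLF site were also not called when the footprint had to cover the whole match, with C/EBP shares of 23.6% and 20.5% against 5.56% and 5% (exact adjusted p = 0.0594 and 0.0676). The 4 below were ETS (39.0% for the reversed consensus), NF-kB (54.8%), EBF (53.2%) and MYB (31.0%), of which ETS was no longer called with the longer peak lists. For RUNX the adjusted p was 2.71e-33 and 1.2e-35, and for TCF1/LEF1 7.85e-12 and 6.92e-22. E-box (34.9%), ROR (33.2%) and GATA (25.9%) did not pass. When the footprint had to cover the whole match, GATA was called below its reversed consensus, with a mean ratio of 0.609. The reversed CTCF consensus had only 7 matches in replicate 1, and REST could not be tested for lack of them.

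**Figure D5:**
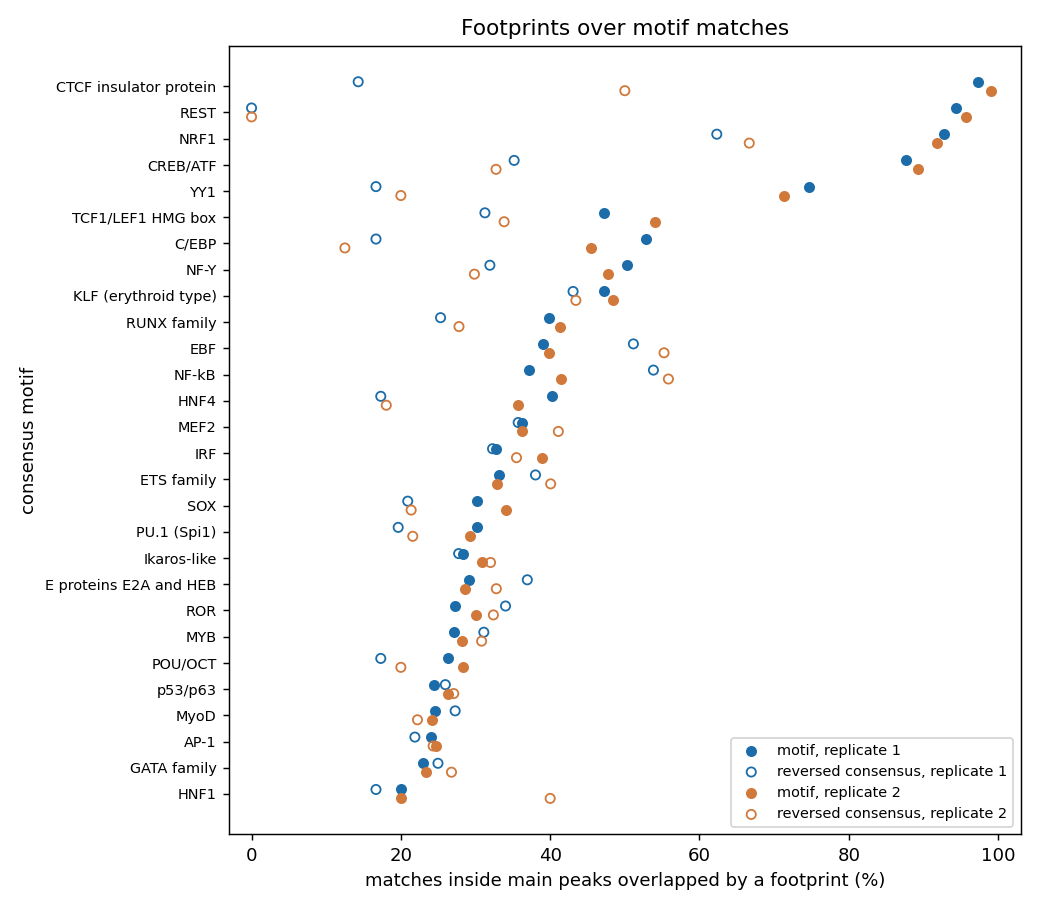
Share of motif matches inside main-list peaks that a deposited footprint overlaps, in percent, for each consensus (filled points) and its reversed form (open points), 1 pair per replicate. CTCF lies at 97.2% and 99.1%, RUNX at 39.8% and 41.3% against 25.3% and 27.8% for its reversed form.

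The deposited lists held 303466 footprints in replicate 1 and 438339 in replicate 2, with a median width of 11 bp in both. In replicate 1, 71.4% of them lay in main-list peaks, and in replicate 2, 65.4%, while 89.6% and 90.6% of these peaks held at least 1 footprint. Of the replicate 1 footprints 72.9% overlapped one of replicate 2 by at least 1 bp, and of the replicate 2 footprints 49.4% overlapped one of replicate 1, against 51.3% and 45.5% for footprints placed at random in shared peaks. The observed shares cover all footprints, also those outside peaks, while the random ones are for shared peaks only, so these sets are unlike. Inside peaks of both replicates, a like comparison, the shares were 76.96% and 68.2% against 46.7% and 42.2%.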

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

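The tests of a single detection limit, of sites closed in replicate 1, of a local threshold, of GC content and of the bases of the motifs, and the genes with clusters of weak peaks, were chosen after the result was seen.

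The lists of cleavage rates, which entered no comparison above, hold signal outside the peaks. Bases listed below an FDR of 0.05 and outside every peak of the longer list came to 16.8 Mb in replicate 1 and 20.03 Mb in replicate 2. Of these bases 81.9% of those in replicate 1 and 68.9% of those in replicate 2 were listed in the other replicate as well, with no chance level computed for bases so close to peaks. They lay beside peaks, with 97.3% and 97.0% within 500 bp of one, and at promoters in 54.6% and 51.3%.

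Counting overlapping windows once, 48 windows of 50 kb on either side of a gene start had at least 30 peaks in replicate 2 and at least 2 times the peaks of replicate 1, among them those of Satb1, Rag2, Ly6e, Nr4a1 and H2-Aa, while the opposite held in 1 window, that of Mroh2a. The excess was mostly made of weak peaks, since the windows held 1835 against 680 peaks in sum, but 775 peaks with a signal of at least 0.80 against 613 in replicate 1 with a signal of at least 1, a limit scaled by the ratio at shared peaks. A single detection limit set by the depth of replicate 2 is argued against, because outside these windows 54.7% of the 44634 peaks of its longer list that were not in its main list had a signal above 0.286, the median of its 1181 peaks in the windows that overlapped none of replicate 1 (extra peaks). Whether the extra peaks were closed in replicate 1 stays open, because 16.7% of them lay in its longer list, while of the other 984 the share with a footprint of replicate 1 was 0.508%, or 0.404 times the 1.26% at positions moved by 1 kb outside all peaks, a low share that decides nothing because 82.4% of the footprints of replicate 1 lay in its longer list. A local threshold of the peak calling that was lower in replicate 2 stays open as well: in 81.2% of the windows the weakest signal of replicate 1 was over 2 times that of replicate 2 after scaling, but the windows were chosen for their excess of peaks, which favours this outcome, so it decides nothing, and a difference between the animals was not tested.

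The lower signal of replicate 2 at shared peaks was general. GC content is argued against as the whole cause, because the median log2 ratio ran from −0.37 to −0.24 over 5 bins of GC content. Whether one factor for every peak plus an added background could account for it stays open, because the ratio still differed by −0.19 between the top 2% of peaks (−0.62) and those between 80% and 90% of mean signal (−0.43), between the bounds set in advance. The ratio also fell with peak strength, from 0.873 in the weakest of 5 bins to 0.709 in the strongest, and no biological explanation was tested.

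Footprints covered most CTCF matches and a minority of ETS matches. The strength of the peaks is argued against as the whole cause, because within 5 bins of peak signal CTCF exceeded ETS by at least 40.6 percentage points. Strength still went with footprints, since the ETS share was 19.1% in the weakest bin and 58.3% in the strongest. The bases of the motif, through the cutting preference of DNase I, stay open: CREB/ATF and NRF1 matches exceeded those of the reversed consensus by 27.8 percentage points or more in the mean of both replicates, but ETS matches in the main lists were footprinted less often than reversed ones (33.0% against 39.0%) and the reversed CTCF consensus had 7 matches in replicate 1. No biological explanation was tested.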

How the results depend on the processing

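The CpG matching, the comparison with the other's longer list and the limit to peaks with a signal of at least 1 were chosen after the data were seen, and the last again called 5 lists higher and 0 lower. No paired analysis was possible because the series has 1 group. The calls of each replicate alone gave the same counts of lists and motifs as both together, except 10 motifs in place of 9 with more footprints than their reversed form in either replicate. Because a call required both replicates, each replicate alone could add calls but not lose any, so this alternative could not show a call to be fragile. The promoter share of peaks was 32.3% to 34.7% with one replicate. The cause was not tested for any change below unless stated.

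The share of shared peaks in replicates 1 and 2 was 87.3% and 70.4% with the longer lists, 86.6% and 86.4% with equal numbers of peaks, 86.1% and 72.1% when a share of 0.5 of each peak had to overlap, and 96.6% and 88.7% against the other's longer list. For footprints it was 54.5% and 37.7% with the reciprocal overlap, taken over all footprints. At random places in shared peaks it was then 13.8% and 12.2% (51.3% and 45.5% in the report). Inside peaks of both replicates the share was 76.96% and 68.2%. The correlation of signals was 0.983 with the longer lists and with equal numbers, 0.979 on ranks and 0.988 without the log. The promoter share was 28.5% with the longer lists, and the window itself set it at 25.3% for 500 bp and 43.0% for 2.5 kb.

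The number of lists with fewer promoter peaks, 7 in the report, was 4 with the longer lists and 2 with CpG matching. Lists with fewer peaks within 50 kb rose from 0 to 1 with matching on gene length, and lists with promoters in only one replicate from 0 to 1 in each direction with the longer lists. The number of less frequent motifs, 7 in the report, was 3 with 100 bp windows, which hold fewer matches, and 3 in promoter peaks. Motifs with more footprints fell from 9 to 5 in distal peaks. Changes of side were counted only for motifs called in the main or the alternative setting. Against flanking sequence the motif ratio changed sides for GATA (0.829), IRF (0.754), OCT (0.714), HNF1 (0.189), NF-kB (1.44), MYB (1.13), C/EBP (4.64) and NF-Y (1.14). In promoter peaks it did so for NF-Y (5.71), HNF4 (1.06) and Ikaros (1.02).

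Over all alternatives, single lists and motifs gave these counts, which include each replicate alone, where no call could be lost. A result counted as unchanged if it kept its call, or if it was uncalled both times, whatever its direction. The B cell list, for example, was uncalled both times but lay above the lists matched on CpG content. For promoter lists 156 were unchanged and 12 lost the call. For peaks around lists 187 were unchanged, 1 lost and 1 gained a call. For motifs at peaks 176 were unchanged, 16 lost the call and the 11 above changed sides. For footprints over motifs 155 were unchanged, 7 lost and 6 gained a call. Of values of named genes, the number of peaks within 50 kb moved by more than the spread of the replicates in 280 and by less or not at all in 140. Promoter signal did so in 31 and 389. It is the highest promoter peak of a gene, so it changes only when that peak is dropped or a higher one is added. With an equal number of the strongest peaks all 84 values stayed. The spread also includes the difference between the libraries, so the 389 say little about stability. The lists hold no value below the caller's limit, and total reads were not used, so no limit set by depth is given.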

Other observations

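All groups in this part were chosen after the data were seen, and no test was made on them. Gene families defined by their symbols differed widely in promoter accessibility. A promoter peak was present at 96.1% of 77 ribosomal protein genes, 97.4% of 39 proteasome subunit genes and 83.8% of 383 zinc finger genes of the Zfp series (mean of both replicates). At the other end were 1.23% of 1134 olfactory receptor genes, 0.459% of 327 vomeronasal receptor genes, 3.77% of 53 keratin genes, 3.91% of 64 defensin genes and 5.77% of 26 killer lectin-like receptor genes. Of 39 genes of the Hox clusters, which pattern the embryo, 9 had a promoter peak in replicate 1 and 12 in replicate 2. Of 8 Gimap genes, GTPases of lymphocytes, 5 and 7 had one, and of 34 H2 genes of the major histocompatibility complex 20 and 22.

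The antigen receptor loci also differed. The Tcra/Tcrd locus held 7.24 peaks per 100 kb in replicate 1 and 8.57 in replicate 2, and the Tcrb locus 5.25 and 8.69, against 2.78 and 3.33 over the genome. Of 113 variable segments of Tcra/Tcrd, 57 and 64 had a peak within 1 kb of their start, and of 22 of Tcrb 12 and 14. The immunoglobulin heavy chain locus had 5.06 and 5.83 peaks per 100 kb and 56 and 62 of 113 variable segments, while the kappa light chain locus held 0.158 and 0.284 per 100 kb and none of its 100 variable segments had a peak, and the lambda locus held 0.502 and 1.00. The Tcrg locus had 2.29 and 2.86. Sequence that is nearly the same between segments can lose reads in mapping, and mappability was not used here.

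The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had promoter peaks with signals of 5.30, 4.65, 3.2 and 3.26 in replicate 1 and 2.93, 3.40, 1.99 and 2.32 in replicate 2. Usp9y and Zfy1 had none. Xist, the gene that silences an X chromosome in females, and its antisense gene Tsix also had promoter peaks, with 1.3 and 1.23 and with 1.17 and 0.663.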
